A study of Mus musculus with 9 samples.

How the data were processed

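Single cells came from the paraventricular nucleus region of juvenile C57Bl6/N mice, per the labels' protocols. The tissue was cut from slices 300 µm thick and dissociated with papain, and cells were captured on a Fluidigm C1 chip with up to 96 chambers. Spike-in RNAs were added at lysis, the cDNA was amplified for 21 PCR cycles and fragmented with Tn5 transposase, per the same protocols. The submitters' processing notes name the mm10 genome and Bowtie, with no version of the aligner. The labels describe 9 of the captured cells, all named as secretagogin-positive. How these cells were chosen from the chambers is not given in the sources used here.

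The authors deposited 1 table of whole-number counts, with 24378 gene rows and 92 spike-in rows for the 9 cells. The values are called molecules here, the term by which the authors named the deposit, and the totals per cell are small. The spike-ins gave 1962 to 2184 in 8 cells and 614 in cell 9, so they do not settle the unit by themselves. How duplicate reads were collapsed is not given in the sources used here. Each column was assigned to a cell by the cell number in its name, and 0 columns were left unassigned. Rows were used as deposited. The table splits 359 symbols over 1207 numbered loci, and for a named gene with several loci the largest row in each cell was taken, since copies can share reads. In 27 rows a date stands in place of a symbol; they hold 132 molecules and were kept in the totals. Gene positions were taken from GENCODE M21 (GRCm38/mm10), in which 21996 of the 23530 symbols of the table were found. The strand setting of the counting is not given in the sources used here, so overlapping antisense genes cannot be separated.

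Levels are molecules per 10000 gene molecules of the cell, without spike-ins. Exact Poisson intervals were computed for counts and exact Clopper-Pearson intervals for shares of cells, both at 95%, and both cover counting error only. A count of 0 was given the limit of 3 molecules divided by the cell's total. This limit is lower than the upper end of the exact Poisson interval for 0, which is 3.69 molecules. A gene counted as detected in a cell with at least 1 molecule, and a list member counted as present in most cells when detected in at least 5 of 9. The replicate in a comparison would be the animal, and none is named, so no p-value or standard error was computed; comparisons of cells with simulated ranges and with Dixon's critical value describe these 9 cells only. Doublets were not called, as 9 cells are too few; marker lists for 10 cell types were summed in each cell instead.

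Cell-to-cell variability was the variance-to-mean ratio after thinning each cell to 1021 molecules, against the 95% range of 1000 simulations with equal shares in every cell, for genes with at least 9 molecules. This step was tested on simulated data. At full depth it recovered 66.8% of 199 tested genes changed by 4-fold in 3 of 9 cells and 100% of 200 changed by 10-fold, and it called 1.91% and 2.29% of unchanged genes. After thinning it recovered 70.5% and 100% of 44 changed genes and called 0% of the unchanged ones. The unchanged genes were drawn from the same equal-share model that sets the range. Their low share of calls was therefore fixed by construction and does not show how the step behaves on real cells. Similarity was the Spearman correlation across genes for each pair of cells.

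Gene lists, marker lists, tests and the rule for named genes were set before the data were examined. The rule named Scgn; the peptide genes detected in at least 5 cells and Crh, Avp, Oxt, Trh, Sst, Ghrh and Th; Slc17a6, Gad1, Gad2 and Slc32a1; up to 4 members of each other list with the highest mean per 10000 molecules, with all SNAP, VAMP and syntaxin-1 paralogs; and the 10 genes with the highest mean and the 10 with the highest variance-to-mean ratio outside mitochondrial and ribosomal-protein genes. Other genes are named as chosen after their values were seen, and 19 further genes looked at in the same way are not named. Some genes that the rule named are not reported here. Alternatives set beforehand were other totals, detection at 2 or 3 molecules, thinning, other definitions of most cells, other markers and minimum counts, and leaving out each cell in turn. Alternatives chosen after seeing the data were scaling by spike-ins, 1 locus per symbol, further detection limits, and leaving out the 4 cells with at least 3 markers of another cell type at 2 or more molecules. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.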

Results

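The mRNA of 9 single cells from the paraventricular nucleus of the mouse hypothalamus was counted as molecules per gene. This nucleus holds the neuroendocrine neurons that release corticotropin-releasing hormone, vasopressin, oxytocin and other hormones. All 9 cells carry the same label, secretagogin-positive, and are called cell 1 to cell 9 after the numbers in their labels. Secretagogin is a calcium-binding protein of the EF-hand family, encoded by Scgn. The mice were 21 to 28 days old. No animal is named for any cell, so the 9 cells were treated as 1 sample, the cells were not used as replicates, and no p-value was computed. Comparisons with simulated ranges describe these 9 cells only. Intervals are exact 95% intervals and cover counting error only.

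The cells differed widely in depth. The gene molecules were 1021 in cell 1, 9573 in cell 2, 10730 in cell 3, 12024 in cell 4, 26466 in cell 5, 3393 in cell 6, 7160 in cell 7, 13176 in cell 8 and 7827 in cell 9, with a median of 9573. The genes with at least 1 molecule had a median of 2816 and reached 5542 in cell 5; cell 6 had 1140 and cell 1 fewer still. The added spike-in RNAs gave 1962 to 2184 molecules in cells 1 to 8, which the column names place on lane 3, and 614 in cell 9, the only cell on lane 4. Lane and cell cannot be separated for cell 9. The mitochondrial share of molecules ranged from 4.31% in cell 9 to 34.2% in cell 6. The limit set for a count of 0 was 29.4 molecules per 10000 in cell 1 and 8.84 in cell 6, but only 1.13 in cell 5. The exact intervals for a count of 0 reached higher, to 36.1, 10.9 and 1.39 in these cells. An undetected gene therefore carries little information in cells 1 and 6.

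**Figure D1:**
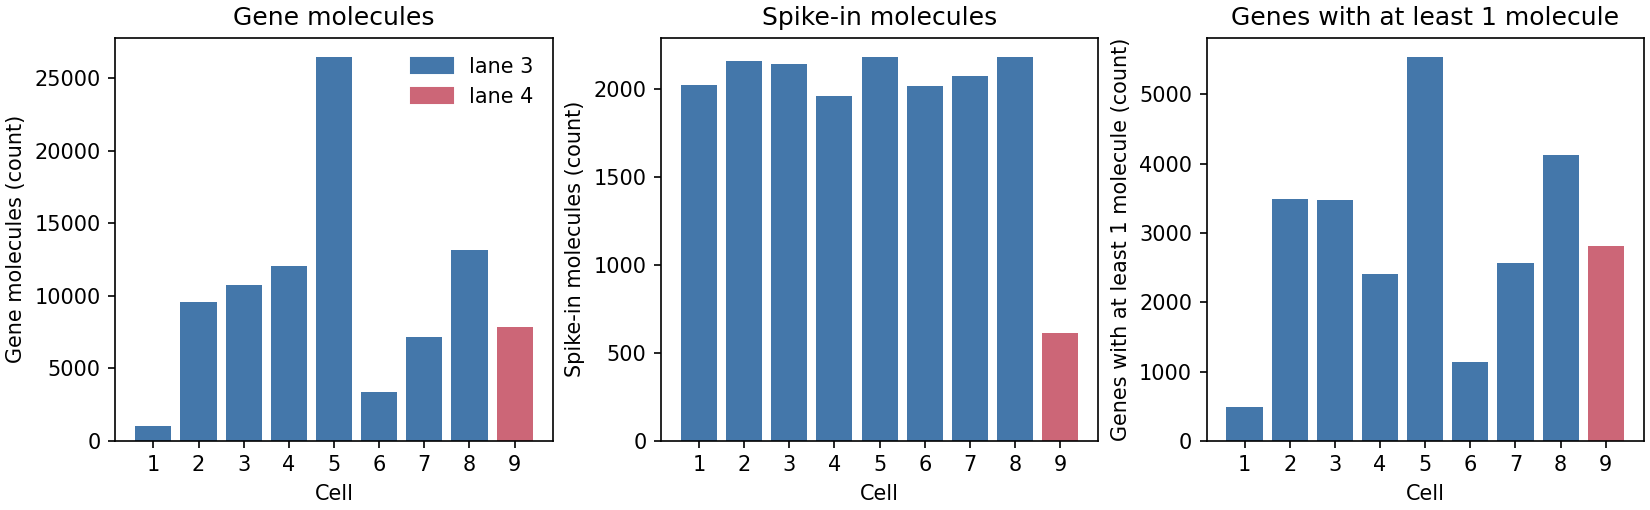
Gene molecules, spike-in molecules and genes with at least 1 molecule (counts, vertical axes) in each of the 9 cells (horizontal axes), with bars coloured by lane. Gene molecules ran from 1021 in cell 1 to 26466 in cell 5, while spike-in molecules lay between 1962 and 2184 in the cells on lane 3.

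The first question was whether the cells held the transcript by which they are labelled. Scgn, on chromosome 13 at 23953456 to 23991214 (minus strand, GRCm38/mm10), was detected in 5 of the 9 cells (55.6%, interval 21.2 to 86.3%). Cell 3 held 11 Scgn molecules, or 10.3 per 10000 (interval 5.12 to 18.3), and cell 8 held 3. Cells 2, 5 and 9 held 1 molecule each, and cells 1, 4, 6 and 7 held none. The limits set for a count of 0 in those 4 cells were 29.4, 2.50, 8.84 and 4.19 molecules per 10000. When detection required at least 2 molecules, Scgn was detected in 2 cells. The labels name the cells by secretagogin, so these counts were read as a check of the labels and not as a finding. How the cells were chosen is not given in the sources used here.

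The second question was which peptide hormones the cells held. Crh, which encodes corticotropin-releasing hormone and lies on chromosome 3 at 19693401 to 19695396 (minus strand), was detected in 4 of 9 cells (44.4%, interval 13.7 to 78.8%). Cell 9 held 19 Crh molecules, or 24.3 per 10000 (interval 14.6 to 37.9), and cell 5 held 13, or 4.91 per 10000 (interval 2.62 to 8.40). Cells 3 and 8 held 2 each. All 4 cells with Crh also held at least 1 Scgn molecule, which 1 further cell held without Crh. Cells 5 and 9, with the most Crh, held only 1 Scgn molecule each. Cells 1, 4, 6 and 7 held neither gene, and cells 1, 6 and 7 were the shallowest of all. In cells 1, 6 and 7 the absence of both genes can therefore not be separated from depth. Cell 4, at 12024 gene molecules, was deeper than cell 9, at 7827, and carried blood and endothelial markers. No link between the 2 genes was tested. Cells 5 and 8 also carried many molecules of glial or ependymal markers, given with the cell type markers, and without cells 4, 5, 7 and 8 there were 2 cells with Crh.

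Sst, the somatostatin gene on chromosome 16 at 23889573 to 23890958 (minus strand), was concentrated in a pair of cells. Cell 3 held 111 Sst molecules, or 103 per 10000 (interval 85.1 to 125), and cell 7 held 29, or 40.5 per 10000 (interval 27.1 to 58.2). Cells 8, 4 and 5 held 5, 2 and 1. Of the cells with Sst, all but cell 3 also carried markers of another cell type, given with the cell type markers. Cell 3, with the most Scgn, was also the cell with the most Sst. Oxt, the oxytocin gene, lies on chromosome 2 at 130576173 to 130577054 (plus strand). It was detected in 8 of 9 cells at 3 to 8 molecules, whatever the depth of the cell, and not in cell 8. Whether each cell made its Oxt or like numbers were added to every chamber cannot be told from these counts. Avp, the vasopressin gene at 130580620 to 130582554 on the same chromosome (minus strand), had 6 molecules in cell 9, 2 in cell 5 and 1 each in cells 4 and 6. Trh and Ghrh, which encode the releasing hormones for thyrotropin and growth hormone, and Th, the rate-limiting enzyme of dopamine synthesis, had no molecule in any cell.

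**Figure D2:**
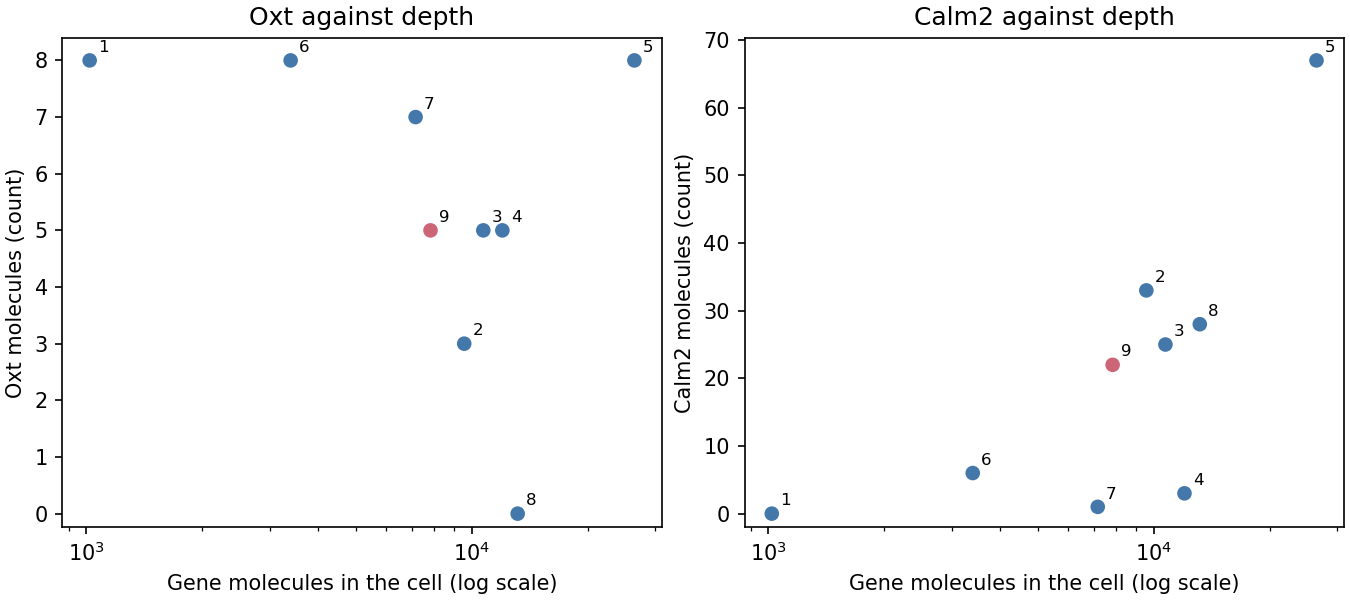
Oxt and Calm2 molecules (counts, vertical axes) against the gene molecules of each of the 9 cells (horizontal axes, log scale), with cell numbers beside the points and colour giving the lane as in the plot of depth. Oxt lay at 3 to 8 molecules in 8 cells, while Calm2 ran from 0 in cell 1 to 67 in cell 5.

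Of the 39 peptide genes listed, 2 were detected in at least 5 cells (Oxt and Sst), 10 in 1 to 4 cells and 27 in none. The peptide genes detected per cell ranged from 1 in cell 1 to 7 in cell 5. The other detected peptides were picked out after their values were seen. Tac1 had 11 molecules in cell 2 and 1 in cell 5, Cartpt had 8 in cell 3 and 3 in cell 8, Pmch had 5 in cell 9 and 2 in cell 5, and Nmb had 5 in cell 8. Penk, Npy, Pomc and Nmu had at most 2 molecules in any cell. The count of 2 peptide genes was 1 when detection required at least 2 molecules. It was also 1 when any 1 of cells 3, 4, 5, 7 and 8 was left out. Sst was detected in exactly these cells, and 5 cells were still required, so that change follows by construction.

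**Figure D3:**
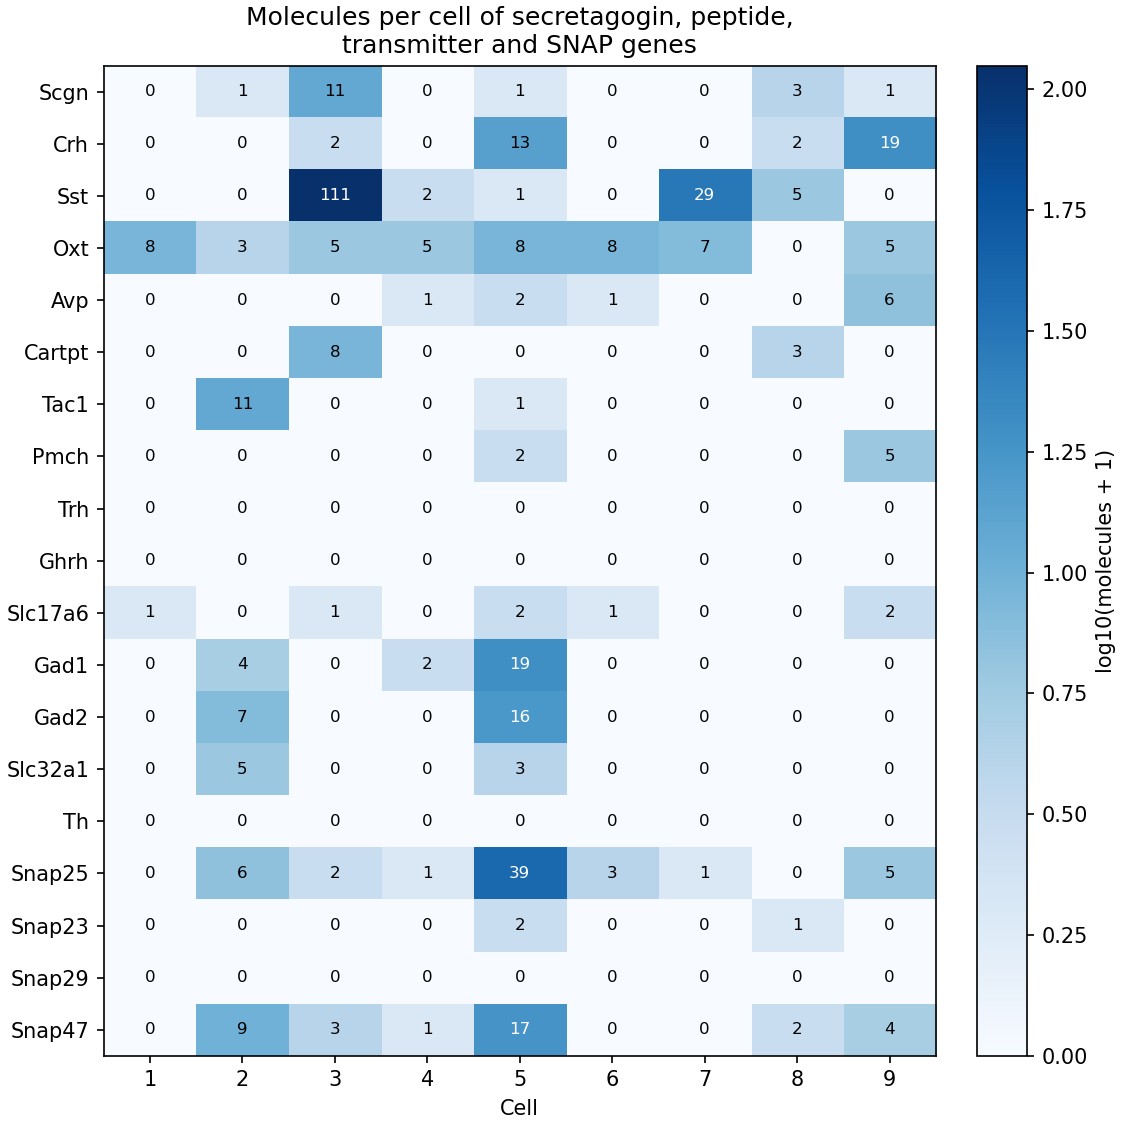
Molecules of secretagogin, peptide, transmitter and SNAP genes (vertical axis) in each of the 9 cells (horizontal axis), with the count printed in each square and colour giving log10(molecules + 1). Cell 3 held 11 Scgn and 111 Sst molecules, cell 9 held 19 Crh molecules, and Oxt was present at 3 to 8 molecules in 8 cells.

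The third question was which fast transmitter the cells would use. Slc17a6, the vesicular glutamate transporter of most hypothalamic glutamate neurons, was detected in 5 cells, at 1 or 2 molecules in each. Gad1 and Gad2, which encode the enzymes of GABA synthesis, and Slc32a1, the vesicular GABA transporter, together had 38 molecules in cell 5, 16 in cell 2 and 2 in cell 4, and none in the other cells. In 4 cells (1, 3, 6 and 9) the molecules of Slc17a6 outnumbered those of the GABA markers, in 3 cells (2, 4 and 5) the GABA markers led, and cells 7 and 8 had neither. Cells 4 and 5 also carried markers of other cell types, and without cells 4, 5, 7 and 8 the GABA markers led in 1 cell. Cell 5 held both kinds, with 2 Slc17a6 molecules. Only 1 cell, cell 9, had at least 2 molecules more of Slc17a6, so the glutamate count rests on single molecules in the other 3 cells. Of the 20 transmitter genes listed, 1 was detected in at least 5 cells, 6 in 1 to 4 cells and 13 in none, and none was in at least 5 cells at 2 or more molecules.

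The fourth question was which parts of the release machinery were present. Of the 15 genes of dense-core vesicles and peptide processing, 9 were detected in at least 5 cells and the other 6 in 1 to 4 cells. Scg2, a granin of dense-core vesicles, was detected in 8 cells with 105 molecules in all, of which 37 lay in cell 9. Scg5, a chaperone of prohormone convertase, had 76 molecules, and Cpe, carboxypeptidase E, had 67, each in 6 cells. Ptprn, a dense-core vesicle membrane protein, was detected in all 9 cells with 42 molecules. All 5 cells with Scgn also held Scg2, Scg5 and Cpe. In cells 2, 5 and 9 this rests on 1 Scgn molecule, and the shallowest cells, 1, 6 and 7, held no Scgn.

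Of the 33 exocytosis genes, 11 were detected in at least 5 cells, 16 in 1 to 4 cells and 6 in none. Among the SNAP genes, which encode SNARE proteins of membrane fusion, Snap25 had 57 molecules in 7 cells, of which 39 lay in cell 5. Snap47 had 36 molecules in 6 cells, Snap23 had 3 and Snap29 had none. Among the vesicle SNAREs, Vamp2 had 16 molecules, Vamp3 had 9 with 8 of them in cell 4, Vamp7 had 7, Vamp4 had 5 and Vamp1 had 2. Stx1a had none. Of the synaptotagmins, Syt11 had 63 molecules and Syt4 had 42, each in 8 cells. When detection required at least 3 molecules the count of 11 was 2, and after thinning every cell to 1021 molecules it was 0.

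Some other genes for calcium-binding proteins had more molecules than Scgn, which had 17 in all, and others of the list had fewer. The calmodulin genes Calm2 and Calm3 had 185 and 73 molecules, each in 8 cells, and Calb1, which encodes calbindin, had 26 in 6 cells. Of the 16 genes of this list, 7 were detected in at least 5 cells, 8 in 1 to 4 cells and 1 in none, and 4 were in at least 5 cells when detection required at least 2 molecules. Of the 7 transcription factors of the paraventricular nucleus, Pou3f2 was detected in 5 cells with 10 molecules in all, and no member was in at least 5 cells at 2 or more molecules. Arnt2 had 7 molecules in cell 9 and 4 in cell 8, Sim1 had 1 in each of the same cells, and Uncx had 1 each in cells 3 and 7. Of the 17 transcription factors of other forebrain and hypothalamic neurons, none was detected in at least 5 cells and 7 were detected in 1 to 4 cells. Dlx1 had 2 molecules in cell 5 and 1 each in cells 2 and 6, and Six3 had 1 each in cells 2, 3 and 5.

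Among receptors and channels, the AMPA receptor subunit gene Gria2 was detected in 8 cells with 48 molecules, and the glycine receptor subunit gene Glra2 had at most 4 in any cell. Of the 21 ionotropic receptor genes, 3 were detected in at least 5 cells, 14 in 1 to 4 cells and 4 in none. Of the 25 voltage-gated channel genes, the corresponding numbers were 3, 18 and 4, and the sodium channel gene Scn2a1 had 16 molecules in 6 cells. With at least 2 molecules, 1 channel gene was in at least 5 cells. None of the 29 hormone and monoamine receptor genes was detected in at least 5 cells, 14 were detected in 1 to 4 cells, and Adra1b had 6 molecules in cell 6 alone. Without cells 4, 5, 7 and 8, 1 receptor gene was in at least 3 of 5 cells. Of the 9 genes of glucocorticoid signalling, 3 were detected in at least 5 cells. Nr3c1, the glucocorticoid receptor gene, had 26 molecules in 7 cells, Hsp90ab1 had 293 in all 9 cells, and Tsc22d3 had 15 in 5 cells. Of the cells with Tsc22d3, all but cell 2 also carried markers of another cell type. Without cells 4, 5, 7 and 8, 2 genes of this list were in at least 3 of 5 cells.

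Immediate early genes, which neurons induce on activity and which enzymatic dissociation also induces, were widespread. Of the 16 genes of this list, 11 were detected in at least 5 cells and the other 5 in 1 to 4 cells, and 7 were in at least 5 cells at 2 or more molecules. Fos had 129 molecules and Jun had 97, each in all 9 cells, Egr1 had 98 in 8 cells and Fosb had 53 in 8 cells. The list took 2.07% of molecules in cell 7, 1.05% in cell 8 and 0.151% in cell 5, with a median of 0.690%. Cells 5, 7 and 8 all carried markers of another cell type, so the highest and the lowest share both lay in such cells.

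The last question was whether each chamber held a neuron alone. The neuron markers took a median of 1.12% of molecules, from 0.258% in cell 8 to 6.07% in cell 1, and a median of 0.321% without the most abundant marker, Meg3, which gave 413 of the 904 neuron-marker molecules. In cell 1, 61 of the 62 neuron-marker molecules came from Meg3, which is a long non-coding RNA. Without Meg3, the neuron-marker molecules were 1 in cell 1, 8 in cell 6, 9 in cell 4, 22 in cell 8 and 23 in cell 7. They were 48 in cell 3, 60 in cell 9, 64 in cell 2 and 256 in cell 5. Stmn3, Stmn2 and Celf4 had 108, 59 and 43 molecules in all. In cells 4, 5 and 8 another marker list had more molecules than the neuron list. Cell 4 held 2376 molecules of blood markers, 19.8% of its total, with 1224 from the beta-globin gene Hbb-bs and 1143 from the alpha-globin gene Hba-a2. The 2 numbered loci of Hba-a2 had 1139 and 1143 molecules, and whether the same reads were counted at both is not known. The blood-marker sum uses 1 locus and the total of cell 4 holds both. The alpha-globin level, that total and the blood share are therefore uncertain. Cell 4 also held 118 molecules of endothelial markers, with 63 from Itm2a and 26 from Slco1a4.

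Cell 5 held 397 molecules of oligodendrocyte markers against 297 of neuron markers, among them 35 from Mbp, which encodes myelin basic protein, and 26 from Mog. Cell 8 held 310 molecules of ependymal and tanycyte markers against 34 of neuron markers, with 231 from Dbi and 25, 24 and 20 from Tmem212, Ccdc153 and Rarres2. It also held 30 molecules of astrocyte markers, with 10 from Gja1, 8 from Aqp4 and 7 from Sox9. Cell 7 held 54 molecules of endothelial markers, with 22 from Ly6c1 and 18 from Itm2a, against 98 of neuron markers. Of those 98, 75 came from Meg3. No microglial marker had a molecule in any cell. The lists for oligodendrocyte precursors, mural cells and fibroblast-like cells had 4, 12 and 2 molecules over all cells. Leaving out the most abundant marker of each list gave cells 4, 7 and 8 as those in which another list led.

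**Figure D4:**
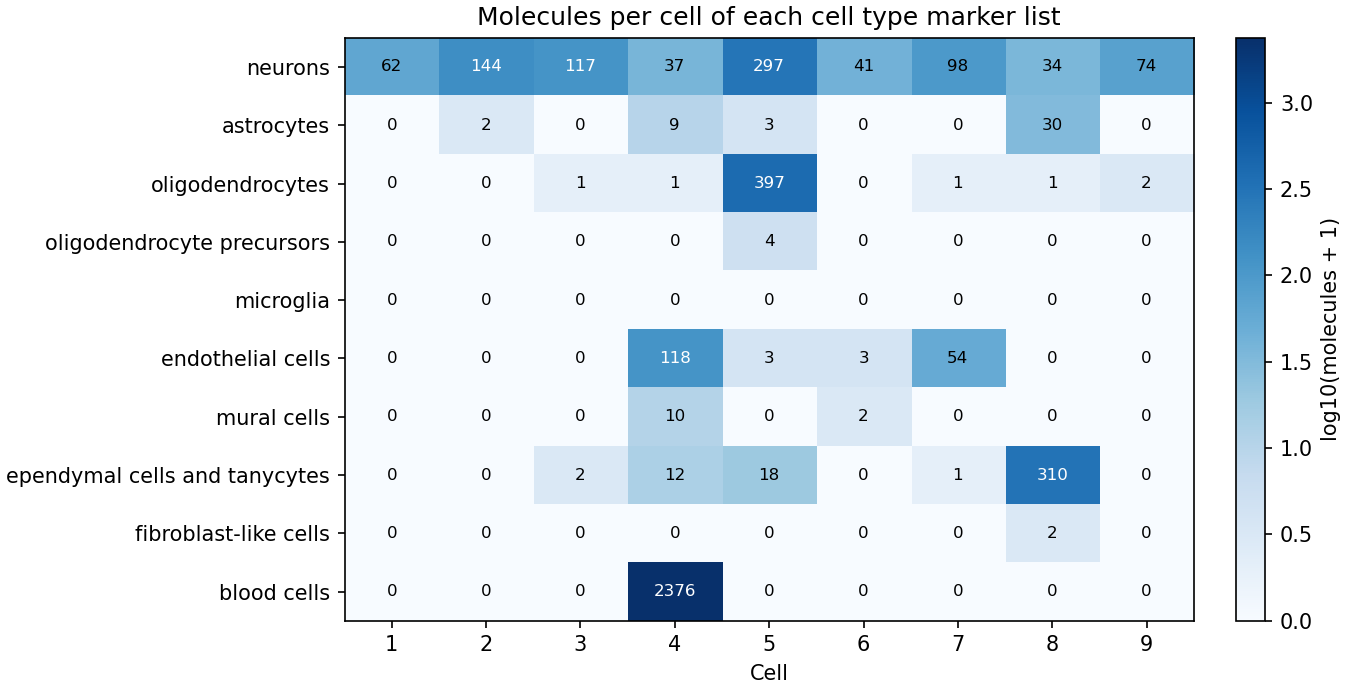
Molecules of each cell type marker list (vertical axis) in each of the 9 cells (horizontal axis), with the count printed in each square and colour giving log10(molecules + 1). Blood markers reached 2376 molecules in cell 4, oligodendrocyte markers 397 in cell 5 and ependymal markers 310 in cell 8.

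After thinning every cell to 1021 molecules, 46 of the 91 genes with at least 9 molecules lay above the range of simulated cells with equal shares. Of the 27 genes with symbols starting with mt-, or with Rpl or Rps and a digit, 20 lay above the range. Among them mt-Tc, a mitochondrial transfer RNA picked out after its value was seen, had the highest variance-to-mean ratio, 44.2. Of the 64 other genes, 26 lay above the range. These others include the ribosomal-protein genes Rplp1 and Rplp2, both within the range. Among the other genes, Hbb-bs had the highest variance-to-mean ratio, 93.0, followed by both Hba-a2 loci. Meg3 reached 33.7, Malat1 31.1, Dbi 21.0, Hbb-b2 17.0, Pisd-ps3 11.9 and Sst 7.14. A gene whose thinned molecules all lie in 1 cell has a ratio equal to their number. That was so for Hbb-bs, both Hba-a2 loci, Hbb-b2 and Dbi. The globin genes were detected in cell 4 alone, and 231 of the 254 Dbi molecules lay in cell 8. These ratios restate the blood and ependymal markers of those cells. No run left out cells 4, 5, 7 and 8 together. Without thinning, 821 of 2063 genes lay above the simulated range. The most abundant genes outside the mitochondrial and ribosomal-protein genes included Malat1, Meg3, Snhg11, Hsp90aa1 and Resp18, a gene of neuroendocrine secretory granules with 107 molecules in cell 5 and none in cells 1, 4 and 6. The Spearman correlation across 2063 genes had a median of 0.154 over the 36 pairs of cells, from 0.00678 to 0.454, the latter between cells 3 and 5. The median was 0.253 after thinning every cell to 1021 molecules, where 91 genes had at least 9 molecules. Thinning thus changed the depth and the set of genes together. The median was 0.266 for genes with at least 45 molecules and 0.247 as a Pearson correlation of log2(molecules per 10000 + 1). Genes are not independent replicates.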

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

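All tests of explanations in this part were chosen after the results were seen, and in the first pattern 1 simulation was run after the outcome of another was known. Of 141 measures given for the 9 cells, 76 had 1 cell far from the others, with a gap to the nearest cell above Dixon's 95% critical value for the range of the group. Among 19 further genes that were looked at and are not named, 14 more did, which makes 90 of 160. Chance gives about 1 in 20 groups of well-behaved values, but counts that are 0 in most cells meet this rule often, so the number of such genes is no measure of how different the cells are.

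Cell 1 stood apart in molecules per 10000 with 78.4 of Oxt, 9.79 of Slc17a6, 597 of Meg3, 9.79 of Glra2, 9.79 of Cacna1c and 137 of Pisd-ps3, and with 6.07% of molecules from the list for neurons. Cell 2 stood apart in molecules per 10000 with 5.22 of Slc32a1, 2.09 of Penk, 11.5 of Tac1 and 1.04 of Nmu, and with 0.0836% of molecules from the list for transcription factors of other forebrain and hypothalamic neurons. Cell 3 stood apart in molecules per 10000 with 10.3 of Scgn, 103 of Sst and 7.46 of Cartpt. Cell 4 stood apart in molecules per 10000 with 4.16 of Agt, 52.4 of Itm2a, 21.6 of Slco1a4, 6.65 of Rgs5, 0.832 of Vtn, 0.832 of Myl9, 1018 of Hbb-bs, 951 of Hba-a2, 7.49 of Alas2, 5.82 of Sgk1, 6.65 of Vamp3, 951 of Hba-a2_loc2, 947 of Hba-a2_loc1, 109 of Hbb-b2 and 606 of mt-Tc, and with 19.8% of molecules from the list for blood cells. Cell 5 stood apart in molecules per 10000 with 13.2 of Mbp, 9.82 of Mog, 5.29 of Cnp, 1.51 of Olig1, 6.42 of Tsix, 0.756 of Vamp1 and 0.756 of Pomc, and with 1.5% of molecules from the list for oligodendrocytes and 0.0151% of molecules from the list for oligodendrocyte precursors. Cell 5 also stood apart with 26466 gene molecules. Cell 6 stood apart in molecules per 10000 with 5.89 of Tagln, 2.95 of Dlx1, 17.7 of Adra1b, 2.95 of Insr, 8.84 of Scn2a1 and 11.8 of Ddx3y, and with 0.236% of molecules from the list for hormone and monoamine receptors. Cell 7 stood apart in molecules per 10000 with 30.7 of Ly6c1, 4.19 of Ghr, 39.1 of Fosb and 33.5 of Cyr61, and with 2.07% of molecules from the list for immediate early and dissociation stress. Cell 8 stood apart in molecules per 10000 with 7.59 of Gja1, 6.07 of Aqp4, 5.31 of Sox9, 175 of Dbi, 19 of Tmem212, 18.2 of Ccdc153, 15.2 of Rarres2, 1.52 of Col1a2, 3.79 of Nmb and 47.1 of Mt1, and with 0.228% of molecules from the list for astrocytes and 2.35% of molecules from the list for ependymal cells and tanycytes and 0.0152% of molecules from the list for fibroblast-like cells. Cell 9 stood apart in molecules per 10000 with 24.3 of Crh, 7.67 of Avp, 47.3 of Scg2, 20.4 of Calm3, 8.94 of Arnt2, 2.56 of Vamp4 and 6.39 of Pmch, and with 1.28% of molecules from the list for dense-core vesicle and peptide processing and 0.128% of molecules from the list for paraventricular transcription factors. Cell 9 also stood apart with 614 spike-in molecules. Several of these values rest on 1 to 3 molecules, and in cells 1 and 6 a single molecule equals 9.79 and 2.95 per 10000.

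The first pattern is Scgn at 0 in 4 cells labelled secretagogin-positive. In 15.05% of 10000 simulations with one Scgn share in all 9 cells, at least 4 cells held 0, so sampling of a low-abundance transcript could give the zeros. A second simulation, run after that value was known, left out cell 3, the cell with the most Scgn, and gave 73.08%; leaving out a cell for its own count makes that simulation easier to meet. One share for all cells does not hold for cell 3, whose 11 molecules stand against 2.00 expected (index of dispersion 6.09 against a simulated upper bound of 2.44). In 3 cells the only evidence is 1 molecule, and single Scgn molecules from free RNA or barcode cross-talk cannot be told apart from expression there, since 1 molecule has no second count to compare.

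The second pattern is markers of another cell type in cells 4, 5, 7 and 8. An equal spread of free RNA over all chambers is argued against. At least 95.5% of the molecules of each of the lists for blood cells, oligodendrocytes, ependymal cells and tanycytes, endothelial cells and astrocytes lay in these cells. The upper bound of the simulated 95% range was 70.5% for the 4 highest of 9 equal chambers. Cells and lists were both picked from these same counts. The bound allows for the choice of cells but not of lists, so the share partly restates the pattern. 2 cells, or a cell with attached material, in 1 chamber stays open. Cell 5 had 2.01 times the molecules of the next deepest cell. Per spike-in molecule it had 12.1, against 6.13 in cell 4 and 6.04 in cell 8, the next highest on lane 3. The total of cell 4 holds both Hba-a2 loci, at 1139 and 1143 molecules, which may count the same reads. Cell 9, alone on lane 4 and with only 614 spike-in molecules, had 12.7. Cells 4 and 8 had 12024 and 13176 gene molecules against 10730 in cell 3, and cell 7 had 7160 against a median of 9573. Depth cannot separate 2 cells from 1 large cell. No biological explanation was tested, as the labels give 1 group.

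The third pattern is Oxt at a like number of molecules in cells of different depth. Oxt at one share of every cell's molecules is not what these counts show. The index of dispersion around depth was 17.0, against 2.32 as the upper bound of the simulated 95% range. Oxt was picked for like counts at unlike depth, so this index restates the pattern too. The shallowest cells, 1 and 6, held 8 molecules each, at 78.4 and 23.6 per 10000. Cell 5, the deepest, also held 8, at 3.02 per 10000. The same number of Oxt molecules added to every chamber and Oxt made by each cell at its own level cannot be told apart. The index around one mean was 1.34 (simulated 95% range 0.281 to 2.26). It was the lowest among the 315 genes with at least 40 molecules, and the second lowest was 1.75. Oxt was picked for its like counts, so this value and its rank restate the pattern. Cell 8 held 0, and with a mean of 5.44 molecules the chance that any of 9 chambers holds 0 is 3.82%.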

How the results depend on the processing

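No comparison between groups exists, and no paired analysis was possible because the labels give 1 group. Small counts of cells and genes move by over 1.5 times with a change of 1 or 2. The cells with Crh, 4 as reported, were 2 with at least 3 molecules, 2 after thinning to the shallowest cell and 2 without the cells with markers of another cell type. The cells with Scgn, 5 as reported, were 2 with at least 2 molecules, 2 with at least 3, 1 after thinning and 3 without the cells with markers of another type, all chosen after seeing the data. The peptide genes in most cells, 2 as reported, were 1 with at least 2 or 3 molecules, 1 after thinning and 1 without the cells with other markers. They were 1 in at least 7 of 9 cells and 4 in at least 3 of 9. Leaving out each cell in turn, with 5 cells still required, gave 1 to 2. The exocytosis genes, 11 as reported, were 2 with at least 3 molecules, 0 after thinning, 19 in at least 3 of 9 cells and 4 in at least 7 of 9. With at least 2 molecules, a setting added later, the lists gave 0 in place of 1 for neurotransmitter markers, 4 in place of 7 for calcium-binding proteins, 0 in place of 1 for paraventricular transcription factors, 1 in place of 3 for voltage-gated channels and 7 in place of 11 for immediate early genes. Hormone and monoamine receptors gave 1 in place of 0 without the cells with other markers. The cells with more Slc17a6, 4 as reported, were 1 with at least 2 molecules more and 1 after thinning; those with more GABA markers, 3 as reported, were 1 after thinning and 1 without the cells with other markers. The genes above the simulated range, 46 as reported, were 821 without thinning, where 2063 in place of 91 genes were tested, and 28 with at least 18 molecules, where 34 were. The median correlation of 0.154 was 0.266 with at least 45 molecules and 0.247 as a Pearson correlation on the log2 scale. After thinning it was 0.253, over 91 in place of 2063 genes. The fewer molecules after thinning and the stricter limits account for lower counts by construction; other causes were not tested. The mean Scgn level of 1.69 per 10000 was 0.622 without cell 3, so it rests on cell 3. It was 1.09 after thinning and 2.51 without the cells with other markers. The median neuron marker share of 1.12% was 0.321% without the most abundant marker of each list, so it rests on Meg3. The SD over cells (3.30 and 1.75) exceeds each value and sets no useful limit on its stability. Median depth lay between 8542 and 11733 over the alternatives run for it, and the cells in which another list led numbered 2 or 3. Thinning to 1021 molecules limits every call to abundant genes.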

Other observations

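These values were picked out after they were seen and carry no test. Of the 9779 genes detected in any cell, 46 were detected in all 9, of which 16 were mitochondrial, 2 encoded ribosomal proteins and 28 were others, among them Malat1, Meg3, Fos, Jun, Ptprn, Hsp90ab1 and Snhg11. Otp, a transcription factor needed for the development of neuroendocrine neurons in this nucleus, and the receptor genes Oxtr and Avpr1a had no molecule in any cell.

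Mitochondrial transfer RNAs took 15.0% of the molecules of cell 4, 3.80% in cell 7 and 0.240% in cell 2. In cell 4, 729 of these molecules were mt-Tc, which had 164 in cell 8 and 84 in cell 7. The metallothionein gene Mt1 had 62 molecules in cell 8, which also held the ependymal and astrocyte markers, 16 in cell 5 and 15 in cell 4. Cyr61, an immediate early gene, had 24 molecules in cell 7, 11 in cell 4 and 3 in cell 8.

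Among sex-chromosome transcripts, the Y-linked gene Ddx3y was detected in 7 cells with 16 molecules in all, Eif2s3y in cells 2 to 5 and Kdm5d in cells 5, 8 and 9, so that cells 2 to 9 each held a Y-linked molecule. Xist had no molecule in any cell. Tsix, which is antisense to Xist and overlaps it on chromosome X, had 17 molecules in cell 5 and none elsewhere, and without a stated strand setting the counts of this overlapping pair are uncertain.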
